A study of Homo sapiens with 17 samples.

How the data were processed

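RNA sequencing was done on 17 human libraries. Of these, 11 came from cells sorted along the path from embryonic stem cells to pancreatic islet cells, and 6 came from a knockdown experiment. The lineage groups were H9 human embryonic stem cells (ES, 2 libraries), definitive endoderm (DE, 2), pancreatic progenitors (PP, 3), islet beta cells (2) and islet alpha cells (2). The knockdown groups were WT, DEANR1KD and FOXA2KD, with 2 libraries each. Per the labels, the stem cell derivatives were sorted by the surface proteins SSEA4, CD184, CD117, CD24 and CD49f, and the islet cells by the antibodies HPi2 and HPa1. The protocol text on every library describes amplified cDNA from sorted cells and paired-end sequencing of pooled, barcoded libraries. The same protocol text is on the knockdown libraries, and the knockdown reagent is not given in the sources used here.

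The deposited values are FPKM, fragment numbers that the authors had already scaled to transcript length and to each library's mapped fragments. The submitters' processing notes name Bowtie, TopHat2 2.0.2, Cufflinks 2.0.2 and the hg19 genome build; options, annotation and the role of each tool are not given in the sources used here. The lineage gene table held 16316 genes, each above 0.5 FPKM in at least 1 library, with 0.501 as the lowest maximum of any gene. A separate lineage table held 39024 lncRNA transcripts, of which 22207 were at 0 in every library. The knockdown table held 23284 genes. All 16316 symbols of the lineage gene table were also in the knockdown table, and 12 of them were listed more than 1 time. The lncRNA table carries 18912 Ensembl identifiers, 18984 assembled transcripts named TCONS and 1128 islet transcripts named HI-LNC. Of the transcripts, 17460 were given a gene name from GENCODE 29 by identifier, while positions were kept as the files give them in hg19. Strand is not in the files, so an lncRNA that overlaps a listed gene can hold fragments of that gene.

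The number of fragments behind each library is not in the files. It was estimated from the smallest step between FPKM values, read as 1 fragment. For the lineage libraries 253 lncRNA transcripts over 4000 bases that lay apart from other transcripts were used, and for the knockdown libraries 133 low genes with 1 GENCODE transcript. The estimates ran from 11.1 to 25.7 (units of 1e6 fragments) in the lineage libraries and from 21.4 to 23.1 in the knockdown libraries, so that 1 fragment on a transcript of 2 kilobases corresponds to 0.019 to 0.045 FPKM. An exact 0 in these tables can be a failed estimate as well as an absent transcript. SDHA, GUSB, HPRT1 and TBP, which are expressed in most cells, were at or near 0 in single lineage libraries. A gene is therefore described as listed at 0, with the value of each library in place of a mean.

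Every table was fitted by itself with limma 3.58.1 in R 4.3.3, with all groups of the table in the fit and moderated variances with a trend on the mean level. Values entered as log2(FPKM + 1), for genes with at least 1 FPKM in at least 2 libraries of the table: 13753 lineage genes, 2924 lncRNA transcripts and 13195 knockdown genes. Differences are on this scale, where the added 1 shrinks differences between low values. Tests were two-sided. P values were adjusted by Benjamini and Hochberg over the features tested in a table and contrast, and features at an adjusted p under 0.05 were called. The lineage contrasts were DE against ES, PP against DE, alpha against PP, beta against PP and beta against alpha, in the gene table and in the lncRNA table. The knockdown contrasts were each knockdown against WT and the knockdowns against each other. Errors are the SD between libraries for levels and the standard error of the fit for log2 differences.

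In addition, 24 lists of genes for cell types, pathways and controls were tested wherever at least 4 members were tested. Camera was used with a preset correlation of 0.01 between genes and again with the correlation estimated from the data, and fry as a self-contained test, with adjustment over the lists of a contrast. For each list, members called over all genes were counted, and members called with p values adjusted over the list alone. Genes called between DE and ES with a difference of at least 1 formed a DE-high and an ES-high signature, which were tested in the knockdown table. Features called against each of the other 4 lineage groups, with a difference of at least 1 each time, were counted as stage-high. For the overlap between the knockdowns, which share their WT libraries, 100 simulated data sets of unchanged groups were set against the same WT libraries. They gave the values that shared controls produce where no gene changes.

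The comparisons, the lists, the alternatives and the rule for naming genes were fixed before the data were examined. The rule names FOXA2 and LINC00261 everywhere. In each contrast it names the 10 largest rises and 10 largest falls among called genes with a mean of at least 5 FPKM in the higher group and no overlap between the groups (5 each and 2 FPKM for lncRNAs). It adds up to 4 called members of each list, or otherwise up to 2 members with the highest level, and in the knockdown contrasts every tested gene of the FOXA2 neighbourhood. XIST and Y-linked genes are left out. In the knockdown table the largest changes were mostly in entries for small nucleolar RNAs and microRNAs, so the same rule was applied a further time without those entries. That step and other names outside the rule were chosen after the values were seen and are described so.

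The alternatives covered the pseudocount, the filter, quantile and upper-quartile scaling, moderation without a trend, a fit of only the groups compared, a minimum difference, a block for the replicate number and leaving out each library. Where a library was left out of a pair, the lone remaining library was assumed to vary like the other groups. The pipeline was tested on simulated data in which changes of known size were added to 50 genes at a time. Between DE and ES, 2% of added changes of 2 (log2) and 86% of added changes of 6 were called; in the FOXA2 knockdown 90% of added changes of 1 were called. The labels do not say whether libraries of a group are separate cultures or donors, so every p value measures only the spread between these libraries, which can be technical.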

Results

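RNA sequencing gave FPKM values for 17 human libraries. The lineage series held embryonic stem cells (ES, n = 2), definitive endoderm (DE, n = 2), pancreatic progenitors (PP, n = 3), and sorted islet beta (n = 2) and alpha cells (n = 2), with 1 table of 16316 genes and 1 of 39024 lncRNA transcripts. The knockdown series held WT, DEANR1KD and FOXA2KD libraries (n = 2 each), with a table of 23284 genes. Estimated fragment numbers, in units of 1e6, were 12.9 and 25.7 for ES, 20.2 and 17.2 for DE, 13, 18.9 and 11.1 for PP, 16.4 and 15.2 for beta, and 14.9 and 18 for alpha. For the knockdown experiment they were 22.9 and 22.4 in WT, 23.0 and 21.4 in DEANR1KD and 23.1 and 21.8 in FOXA2KD. The share of the 16316 lineage genes listed at 0 was highest in ES 1 (38.5%), alpha 1 (38.0%) and alpha 2 (39.2%) and ran from 10.4% to 30.9% in the other lineage libraries. In the knockdown libraries 23.3% to 24.2% of the 23284 genes were listed at 0. In the alpha libraries GCG alone took 28.0% and 27.1% of the summed FPKM, and INS took 7.53% and 10.5% in the beta libraries, which lowers every other gene in those libraries.

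FOXA2, a forkhead transcription factor of the endoderm, lies on chromosome 20 at 22561642 to 22566101 in hg19. LINC00261, the gene symbol of the lncRNA DEANR1, lies at 22541192 to 22559280, leaving 2361 bases between them. Both were at or near 0 in stem cells and present in endoderm. FOXA2 was listed at 0 and 0.0168 FPKM in ES, 28.96 and 38.3 in DE, 18.4, 28.3 and 2.31 in PP, 10.8 and 9.54 in beta and 10.6 and 19.8 in alpha. The corresponding LINC00261 values were 0 and 0, 16.4 and 14.7, 14.03, 24.4 and 12.1, 0.727 and 0.872 and 14.9 and 0.0114 FPKM, so the alpha libraries differed from each other far more than the libraries of any other group. FOXA2 rose from ES to DE by 5.09 ± 1.02 on the log2(FPKM + 1) scale (adjusted p = 0.0387, limma), and this call was lost without ES 1, ES 2, DE 1 or DE 2. LINC00261, listed at 0 in both ES libraries and at 16.4 and 14.7 FPKM in DE, was not called (adjusted p = 0.145, limma). The fit takes a common spread for each gene over all lineage groups, so the unlike alpha libraries widened the spread in this test. In the lncRNA table the annotated LINC00261 transcript of 4912 bases was at 8.71 and 10.4 FPKM in DE and 11.4, 13.3 and 2.66 in PP. It was at 0 in both ES libraries and below 0.01 in each islet library. Alpha 1 instead held 16.5 FPKM on an assembled transcript at the same locus. That transcript was also at 8.02 and 4.06 FPKM in DE and 1.15, 11.8 and 9.75 in PP.

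**Figure D1:**
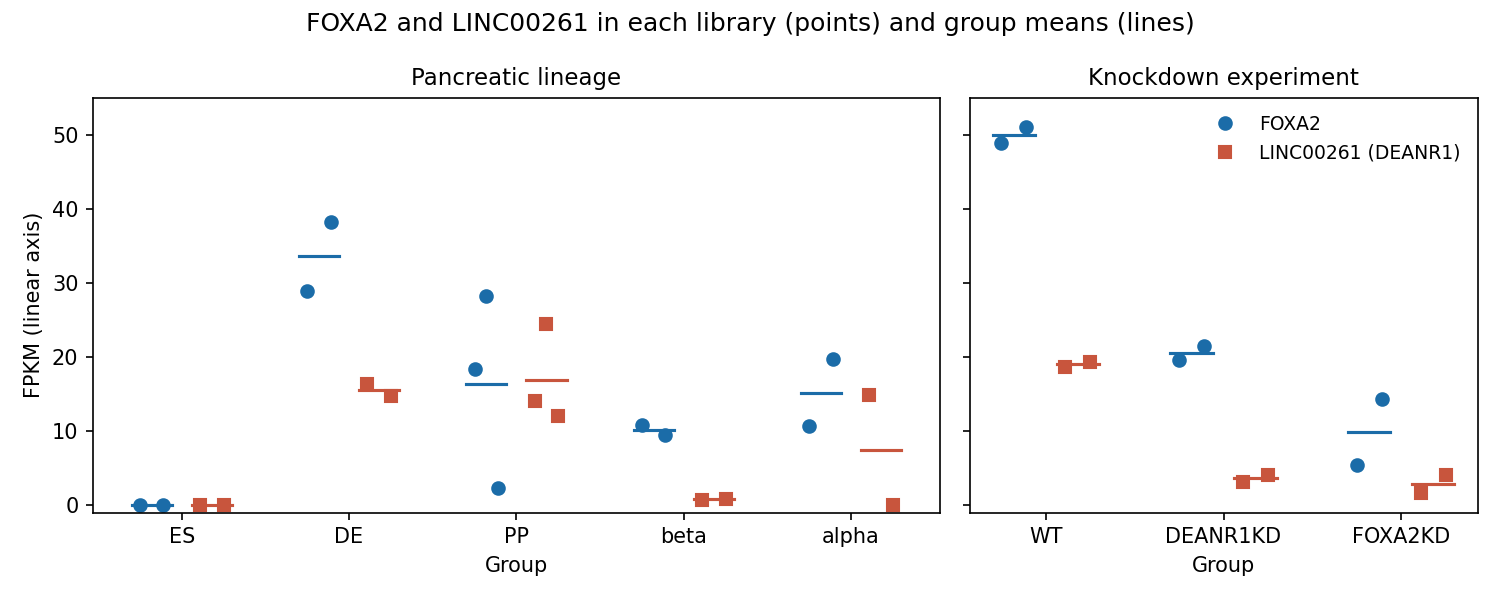
FPKM of FOXA2 and LINC00261, with a point for each library and a line for each group mean. FOXA2 and LINC00261 were at or near 0 in both ES libraries, above 14 FPKM in both DE libraries, and below the WT libraries in all 4 knockdown libraries.

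The comparison of DE with ES asks which genes mark the exit from pluripotency into endoderm. The stem cell factor POU5F1 went from 909 ± 96.3 FPKM in ES to 0.197 ± 0.0229 in DE (SD, n = 2 each), a log2 difference of -9.57 ± 0.71 (adjusted p = 0.000362). The secreted Nodal and WNT antagonist CER1 went the other way, from 13.3 ± 0.550 to 11179 ± 1313 FPKM (9.61 ± 0.80, adjusted p = 0.000362), and became the most abundant transcript of the DE libraries. FGF17 rose from 0.145 ± 0.00025 to 1145 ± 290.1 FPKM (9.94 ± 0.82). The retinoic acid hydroxylase CYP26A1 rose by 8.32 and the cystatin CST1 by 9.81. APOA1 reached 2089 and 554 FPKM and APOA2 679 and 1198 in DE, against at most 1.96 FPKM in ES. The natriuretic peptide gene NPPB was at 603 and 546 FPKM in DE and 0.149 and 0 in ES. S100A14 rose by 8.23. CXCR4, which encodes the CD184 antigen used for the sort, was at 412 and 480.5 FPKM in DE and 0 and 2.63 in ES (7.87 ± 1.47, adjusted p = 0.0288). Streak transcription factors were listed at 0 in ES 1 and stood high in DE: GSC at 159 and 114 FPKM, MIXL1 at 136 and 108, EOMES at 66.9 and 73.5 and LHX1 at 26.7 and 25.01. SOX17, a factor of the early endoderm chosen after its values were seen, was listed at 0 in both ES libraries and at 126 and 101 FPKM in DE. GATA6 and GATA4 reached 85.6 and 102 and 43.2 and 46.4 FPKM. Among the falls, SOX2 was at 120.4 and 47.99 FPKM in ES and 0.0205 and 0 in DE, PRDM14 at 19.9 and 54.7 and 0.818 and 0.0522, and the WNT antagonist SFRP2 at 105 and 176 and 0 and 0.0313. The lncRNA gene ESRG fell from 394 ± 67.8 to 1.42 ± 0.0429 FPKM, USP44 from 96.2 ± 0.294 to 0.0242 ± 0.00879 and the tubulin gene TUBA4A from 46.3 ± 17.9 to 0.118 ± 0.0430. The metallothionein MT1X and the cartilage factor LECT1 fell by 6.75 and 6.54, and OLFML3 by 6.01. Of 13753 genes tested, 173 were called, 111 higher and 62 lower in DE, and 1422 passed an unadjusted p under 0.05. Quantile scaling shifted the median change, 0.028, by -0.104. Without ES 1, ES 2, DE 1 or DE 2 the count was 80, 651, 60 or 61, and 12, 3, 14 or 15 of the 35 named genes lost their call.

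The definitive endoderm list rose as a group: 12 of 20 tested members rose and 0 fell, 15 and 0 adjusted over the list alone (camera adjusted p = 2.1e-23, and adjusted p = 0.00415 with an estimated correlation). Of 8 streak and mesendoderm genes 4 rose and 0 fell, 6 and 0 adjusted over the list alone (1.2e-11, and adjusted p = 0.0246 with an estimated correlation). Of 18 pluripotency genes 4 fell and 0 rose; adjusted over the list alone 7 fell and 1 rose (3.88e-09, and adjusted p = 0.0246 with an estimated correlation). In the Nodal and Activin pathway only CER1 was called, while 5 of 19 rose adjusted over the list alone (0.000883, but adjusted p = 0.135 with an estimated correlation). Early hepatic genes were represented by APOA1 and APOA2 alone, also adjusted over the list alone (camera adjusted p = 0.00888, but adjusted p = 0.304 with an estimated correlation). For pancreatic progenitor genes GATA6, GATA4 and FOXA2 rose, also adjusted over the list alone (0.0291, but adjusted p = 0.304 with an estimated correlation). SOX2 and SOX3 fell among 4 neural ectoderm genes, and adjusted over the list alone 2 fell and 1 rose (0.0156, but adjusted p = 0.135 with an estimated correlation). In the proliferation list none of 14 members was called by limma, also not adjusted over the list alone, although the list sat lower in DE (0.00813, but adjusted p = 0.435 with an estimated correlation); CCNB2, for example, was at 145 and 151 FPKM in ES and 57.5 and 71.4 in DE. Among members of the other lists, the WNT target DKK1 reached 15.1 and 22.3 FPKM in DE, LGR5 18.4 and 4.91 and the imprinted gene DLK1 21.03 and 48.1, TFF1 rose to 35.2 and 24.3 from 0 in both ES libraries, and TFAP2C and SCG5 fell by 3.21 and 4.34. The TFF1 call was lost under quantile scaling.

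The comparison of PP with DE follows endoderm toward the pancreas. The fetal liver and yolk sac protein AFP went from 0.749 ± 0.107 FPKM in DE to 2810.4 ± 1082 in PP (n = 3), a rise of 10.57 ± 0.70 (adjusted p = 6.03e-05). CER1 fell from its DE level to 3.25 ± 3.12 FPKM (-11.62 ± 0.73, adjusted p = 6.03e-05). The pancreatic factor PDX1 was at 22.97, 30.9 and 12.6 FPKM in PP against 0.0200 and 0 in DE (4.44 ± 0.77, adjusted p = 0.0115). SOX9 was at 14.4, 42.3 and 11.1 FPKM against 0.369 and 0, and ONECUT2 rose by 3.74. Liver proteins were among the rises: FGB reached 306 ± 65.1 FPKM, AMBP 338 ± 136, TTR 1351 ± 1240.3 and SERPINA1 314 ± 235. The collagenase MMP1 reached 825 ± 366 FPKM, AGR2 616 ± 313 and the galectin LGALS3 737 ± 174. The growth factor IGF2 rose from 2.11 ± 1.32 to 727 ± 236 FPKM. Matrix genes rose unevenly between libraries: DCN was at 218, 61.97 and 795 FPKM and COL3A1 at 203, 70.4 and 445, with PP 2 lowest each time. HAND1, a factor of the mesoderm and trophoblast, was at 164, 34.5 and 481 FPKM, the hormone subunit CGA at 149, 114 and 17.3 and the hindgut factor CDX2 at 88.7, 80.8 and 26.95. TM4SF4 reached 464, 364 and 109 and ALDH1A1 36.8, 81.1 and 56.3 FPKM. Nodal signalling genes left with CER1: LEFTY2 fell by 10.60, LEFTY1 by 8.73 and NODAL, listed at 0 in PP 1 and PP 3, from 497 and 432 FPKM to at most 0.463. GSC, EOMES and FGF8 were listed at 0 in all 3 PP libraries, and the skeletal actin ACTA1 in PP 1 and PP 3. The pluripotency genes GDF3 and TDGF1 fell by 6.97 and 6.95. CYP26A1, FGF17 and NPPB fell by 9.34, 9.09 and 7.14. Of 347 genes called, 214 were higher and 133 lower in PP, and 1665 passed an unadjusted p under 0.05. The median change over all genes was 0.171; upper-quartile and quantile scaling shifted it by -0.153 and -0.195 and gave 187 higher with 144 lower and 192 higher with 162 lower. Without DE 1, DE 2, PP 1, PP 2 or PP 3 the count was 107, 92, 220, 294 or 288, and 15, 18, 7, 5 or 3 of the 45 named genes lost their call; the excess of rises was gone without DE 1 (55 higher, 52 lower) and turned without DE 2 (41 higher, 51 lower).

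Early hepatic genes were the list that rose most, with 12 of 17 members called higher and 13 adjusted over the list alone (camera adjusted p = 1.77e-25, and adjusted p = 0.00659 with an estimated correlation). All 6 called streak genes fell among 8 tested, 7 adjusted over the list alone (3.5e-19, and adjusted p = 0.00659 with an estimated correlation). In the definitive endoderm list 11 of 20 fell and 1 rose, with the same numbers adjusted over the list alone (4.5e-16, and adjusted p = 0.00659 with an estimated correlation). Nodal and Activin genes fell in 8 of 19 cases, also 8 adjusted over the list alone (1.1e-11, and adjusted p = 0.00919 with an estimated correlation). Of 18 pluripotency genes 4 fell, L1TD1, GDF3 and TDGF1 among them, 7 adjusted over the list alone (7.22e-09, and adjusted p = 0.0126 with an estimated correlation). HAND1, CGA and CDX2 rose among 6 trophoblast genes, and adjusted over the list alone 4 rose and 1 fell (0.000799, and adjusted p = 0.0371 with an estimated correlation). DCN, COL3A1 and COL1A2 rose among 12 mesenchyme genes, 8 adjusted over the list alone (1.05e-06, but adjusted p = 0.204 with an estimated correlation). PDX1, SOX9 and ONECUT2 rose among 17 pancreatic progenitor genes, 6 adjusted over the list alone (0.017, but adjusted p = 0.206 with an estimated correlation). TTR, TM4SF4 and ALDH1A1 rose among 17 alpha cell genes, 4 adjusted over the list alone (0.00441, but adjusted p = 0.0525 with an estimated correlation). No duct gene of 9 was called by limma, and 5 rose adjusted over the list alone (0.00353, but adjusted p = 0.204 with an estimated correlation); the keratin KRT19 was at 857 ± 133 FPKM in DE and 1497 ± 53.5 in PP. HAND1 was the called gene of 7 in the mesoderm list (0.00413, but adjusted p = 0.264 with an estimated correlation), and RBP4 and AQP3 rose among 8 genes of other endocrine cells (0.0304, but adjusted p = 0.264 with an estimated correlation). SPINK1 rose in the acinar list, LYZ in the immune list, SLC2A2 in the beta cell list and B2M in the housekeeping list, while PAX6 fell by 3.97. The SLC2A2 call was lost under upper-quartile and quantile scaling, and that on ONECUT2 under quantile scaling.

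Alpha cells were compared with PP to see how far the progenitors stood from mature endocrine cells. Glucagon, GCG, was at 14.4 ± 2.17 FPKM in PP and 123740 ± 17177 in alpha (n = 2), a difference of 12.97 ± 0.56 (adjusted p = 1.16e-06). The granule protein CHGB rose from 0.505 ± 0.175 to 4012 ± 1580.3 FPKM, and CHGA from 9.96 ± 8.25 to 2786 ± 112. SCG5 and the convertase PCSK2 rose by 10.08 and 7.73. The serotonergic factor FEV was at 23.9 and 31.8 FPKM against 0 in all 3 PP libraries, CRYBA2 at 724 and 355 and the vitamin D carrier GC at 926 and 174. Other islet hormones were also present in the alpha libraries: INS at 6026 and 11102 FPKM, PPY at 749 and 4267, SST at 2592 and 776 and IAPP at 1211 and 699.9. The glucose-6-phosphatase gene G6PC2 was at 56.8 and 91.4 FPKM and ERO1LB at 41.8 and 22.2. Of the liver proteins of PP, AFP fell by 10.83, APOA1 by 10.59, VTN by 9.69 and FGB by 8.19, while TTR was higher in alpha by 3.92. GPC3 fell from 1441 ± 206 to 0.251 ± 0.0666 FPKM, ID3 from 776 ± 195 to 0.110 ± 0.0667 and MMP1 from 825 ± 366 to 0.0627 ± 0.0348. IGFBP3, IGF2 and LUM fell by 9.41, 9.21 and 9.05. The cyclin CCNB2 went from 83.1 ± 9.09 to 0.329 ± 0.330 FPKM, and AURKB from 47.1 ± 15.7 to 0.0578 ± 0.00738. PDX1 was at 0.0272 and 0 FPKM and HES1 at 0.103 and 0.0861. Of 2721 genes called, 300 were higher and 2421 lower in alpha, with 4945 under an unadjusted p of 0.05. This split follows the scale: the median change over all tested genes was -1.144, and upper-quartile and quantile scaling, which shifted it by 0.403 and 1.128, gave 488 higher with 1622 lower and 838 higher with 898 lower. Without PP 1, PP 2, PP 3, alpha 1 or alpha 2 the count was 1553, 1522, 1699, 2268 or 1508, and 11, 11, 9, 11 or 13 of the 76 named genes lost their call.

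Endocrine genes rose in alpha as a group, 11 of 15 and 13 adjusted over the list alone (camera adjusted p = 1.63e-25, and adjusted p = 0.00216 with an estimated correlation). Alpha cell genes rose in 10 of 17 cases and fell in 1, the same adjusted over the list alone (1.08e-19, and adjusted p = 0.00133 with an estimated correlation). Of 20 beta cell genes 8 rose and 2 fell, PDX1 among the falls, again the same adjusted over the list alone (2.17e-11, and adjusted p = 0.00218 with an estimated correlation). CD14 rose and LYZ fell among 7 immune genes, the same adjusted over the list alone (0.000301, and adjusted p = 0.0439 with an estimated correlation). Acinar genes including CPB1, REG1A, CTRB2 and CELA3A rose in 6 of 18 cases, 9 adjusted over the list alone and 14 under quantile scaling (7.38e-15, but adjusted p = 0.0981 with an estimated correlation). FOS, JUN, ATF3 and GADD45B rose among 15 immediate early and stress genes, 5 adjusted over the list alone (1.97e-10, but adjusted p = 0.0647 with an estimated correlation). Early hepatic genes fell in 11 of 17 cases, with TTR rising, and 12 fell adjusted over the list alone (8.55e-07, but adjusted p = 0.0823 with an estimated correlation). Of 14 proliferation genes 12 fell, 13 adjusted over the list alone, and 10 or 9 with upper-quartile or quantile scaling (5.63e-07, but adjusted p = 0.121 with an estimated correlation). Mesenchyme genes fell in 9 of 12 cases, 10 adjusted over the list alone (5.38e-06, but adjusted p = 0.203 with an estimated correlation). HAND1, CGA and CDX2 fell among 6 trophoblast genes, 4 adjusted over the list alone (0.0305, but adjusted p = 0.121 with an estimated correlation). KRT19, ANXA4 and TFF1 fell among 9 duct genes, 6 adjusted over the list alone and 1 under either scaling (0.0318, but adjusted p = 0.327 with an estimated correlation). PPY and SST rose while HHEX and AQP3 fell among 8 genes of other endocrine cells (0.0267, but adjusted p = 0.261 with an estimated correlation).

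Beta cells were set against PP in the same way. INS rose from 3.84 ± 3.27 to 36714 ± 5850.4 FPKM (13.10 ± 0.61, adjusted p = 2.9e-06, n = 3 and 2). The peptide gene IAPP rose to 5642 ± 2030.3 FPKM and SST, the hormone of delta cells, to 8249.8 ± 3389. G6PC2, ERO1LB and NPTX2 were at 95.3 and 138, 113 and 97.7 and 187 and 41.5 FPKM. The factor NKX2-2 was at 12.4 and 31.2 FPKM against 0 in all 3 PP libraries, and ghrelin, GHRL, at 65.99 and 51.05 against 0. PAX6 rose from 0.0275 ± 0.00528 to 22.9 ± 1.61 FPKM. PPY, CHGB and SCG5 rose by 10.53, 10.05 and 9.93, and the lncRNA gene MEG3 reached 107 and 41.6 FPKM. Digestive enzymes of acinar cells rose as well: PNLIP went from 0.474 ± 0.382 to 550.2 ± 197 FPKM, PRSS1 from 5.21 ± 1.70 to 2049.9 ± 540.1, CELA3A from 1.27 ± 0.662 to 689 ± 160.4, CPB1 from 0.242 ± 0.0918 to 348 ± 75.5 and CPA1 from 2.17 ± 2.38 to 641 ± 387. The chemokine IL8 was at 117 and 4783 FPKM in the beta libraries. PLVAP, a protein of vessel walls, was at 153 and 97.1 FPKM. AFP, APOA1, APOA2 and VTN fell by 10.81, 10.72, 9.82 and 9.13, IGFBP3 by 9.06, CLDN6 by 8.50 and MFGE8 by 7.73. The cyclin CCNB1 went from 86.5 ± 6.29 to 0.0929 ± 0.0397 FPKM and CDK1 from 82.2 ± 10.8 to 0.0595 ± 0.0254. GATA6 went from 23.2 ± 11.5 to 0.0558 ± 0.00271. Of 1769 genes called, 410 were higher and 1359 lower in beta, with 3945 under an unadjusted p of 0.05. The median change was -0.708; upper-quartile and quantile scaling shifted it by 0.225 and 0.683 and gave 447 higher with 944 lower and 689 higher with 737 lower. Without PP 1, PP 2, PP 3, beta 1 or beta 2 the count was 924, 956, 1037, 1040 or 824, and 11, 13, 10, 16 or 20 of the 76 named genes lost their call.

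Acinar genes rose in beta in 16 of 18 cases, 17 adjusted over the list alone (camera adjusted p = 6.37e-30, and adjusted p = 0.0359 with an estimated correlation). Endocrine genes rose in 12 of 15 cases, and adjusted over the list alone 12 rose and 1 fell (5e-19, and adjusted p = 0.00511 with an estimated correlation). Of 20 beta cell genes 13 rose and 1 fell, 14 and 1 adjusted over the list alone (5.2e-17, and adjusted p = 0.00195 with an estimated correlation). Alpha cell genes rose in 5 of 17 cases and fell in 1, with GCG at 1062 and 4709.5 FPKM; adjusted over the list alone 7 rose and 2 fell (2.64e-05, and adjusted p = 0.0235 with an estimated correlation). Early hepatic genes fell in 11 of 17 cases and rose in 1, 13 and 1 adjusted over the list alone (7.73e-10, and adjusted p = 0.0397 with an estimated correlation). Of 14 proliferation genes 12 fell, 14 adjusted over the list alone, and 10 under either scaling (3.91e-10, but adjusted p = 0.0596 with an estimated correlation). FOS, JUN, ATF3, GADD45B and XBP1 rose among 15 immediate early and stress genes, 6 adjusted over the list alone (9.74e-10, but adjusted p = 0.055 with an estimated correlation). SST, PPY, GHRL and RBP4 rose and HHEX and AQP3 fell among 8 genes of other endocrine cells (6.15e-05, but adjusted p = 0.062 with an estimated correlation). CD14 and TYROBP rose among 7 immune genes, 1 of them under either scaling, and adjusted over the list alone 2 rose and 1 fell (0.00195, but adjusted p = 0.0547 with an estimated correlation). Mesenchyme genes fell in 9 of 12 cases, 7 under either scaling, with COL1A1 and COL3A1 lowest in beta 2 (5.15e-05, but adjusted p = 0.226 with an estimated correlation). HAND1, CGA and CDX2 fell among 6 trophoblast genes (0.0153, but adjusted p = 0.0784 with an estimated correlation).

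Beta and alpha cells, both sorted from islets, were compared directly. GCG was the largest fall, from 123740 ± 17177 FPKM in alpha to 2886 ± 2579 in beta (-5.78 ± 0.61, adjusted p = 0.002). INS stood at 36714 ± 5850.4 FPKM in beta and 8564 ± 3589 in alpha, and this difference was 2.16 ± 0.67 (adjusted p = 0.161). TTR fell from 15717 ± 1689 to 1513 ± 159.6 FPKM and CRYBA2 from 539 ± 261 to 29.2 ± 9.85. The activin subunit INHBA fell by 3.84. ACOT9, PLCE1 and RELB fell by 5.51, 5.33 and 4.62, and the fatty acid receptor FFAR3, at 31.3 and 24.9 FPKM in alpha, was listed at 0 in both beta libraries. SIX3, a beta cell factor, was at 15.7 and 10.6 FPKM in beta, and ghrelin, GHRL, at 65.99 and 51.05; each was listed at 0 in both alpha libraries. The acinar lipase PNLIP was at 550.2 ± 197 FPKM in beta and 1.59 ± 1.36 in alpha, AMY2A at 104 ± 30.2 and 0.0832 ± 0.0106, and CELA2A at 196 ± 71.4 and 3.46 ± 4.67. CEL rose by 2.81, MMP7 was at 81.4 and 43.5 FPKM in beta and 0 in both alpha libraries, and S100A16, CNN3 and KPNA2 by 5.71, 5.66 and 5.53. GP2 was higher by 5.64 and THOP1 lower at -4.62; GP2, THOP1, TTR and CEL were not called under quantile scaling. Of 196 genes called, 163 were higher and 33 lower in beta, with 1681 under an unadjusted p of 0.05. The median change was 0.247; upper-quartile and quantile scaling shifted it by -0.205 and -0.379 and gave 179 higher with 70 lower and 75 higher with 64 lower. Without beta 1, beta 2, alpha 1 or alpha 2 the count was 166, 154, 488 or 182, and 12, 11, 4 or 9 of the 27 named genes lost their call.

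Alpha cell genes sat lower in beta: 4 of 17 fell and 9 adjusted over the list alone (camera adjusted p = 1.5e-13, and adjusted p = 0.00394 with an estimated correlation). Of 20 beta cell genes SIX3 alone was called, and 8 rose adjusted over the list alone (0.000241, and adjusted p = 0.0466 with an estimated correlation). PNLIP, AMY2A, CELA2A and CEL rose among 18 acinar genes, 15 adjusted over the list alone (4.93e-15, but adjusted p = 0.21 with an estimated correlation). GHRL rose among 8 genes of other endocrine cells, 3 adjusted over the list alone (0.00337, but adjusted p = 0.293 with an estimated correlation). No duct gene of 9 was called by limma and 1 rose adjusted over the list alone (0.0425, but adjusted p = 0.645 with an estimated correlation), with KRT19 at 33.8 and 225 FPKM in beta and 44.4 and 0.854 in alpha.

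**Figure D2:**
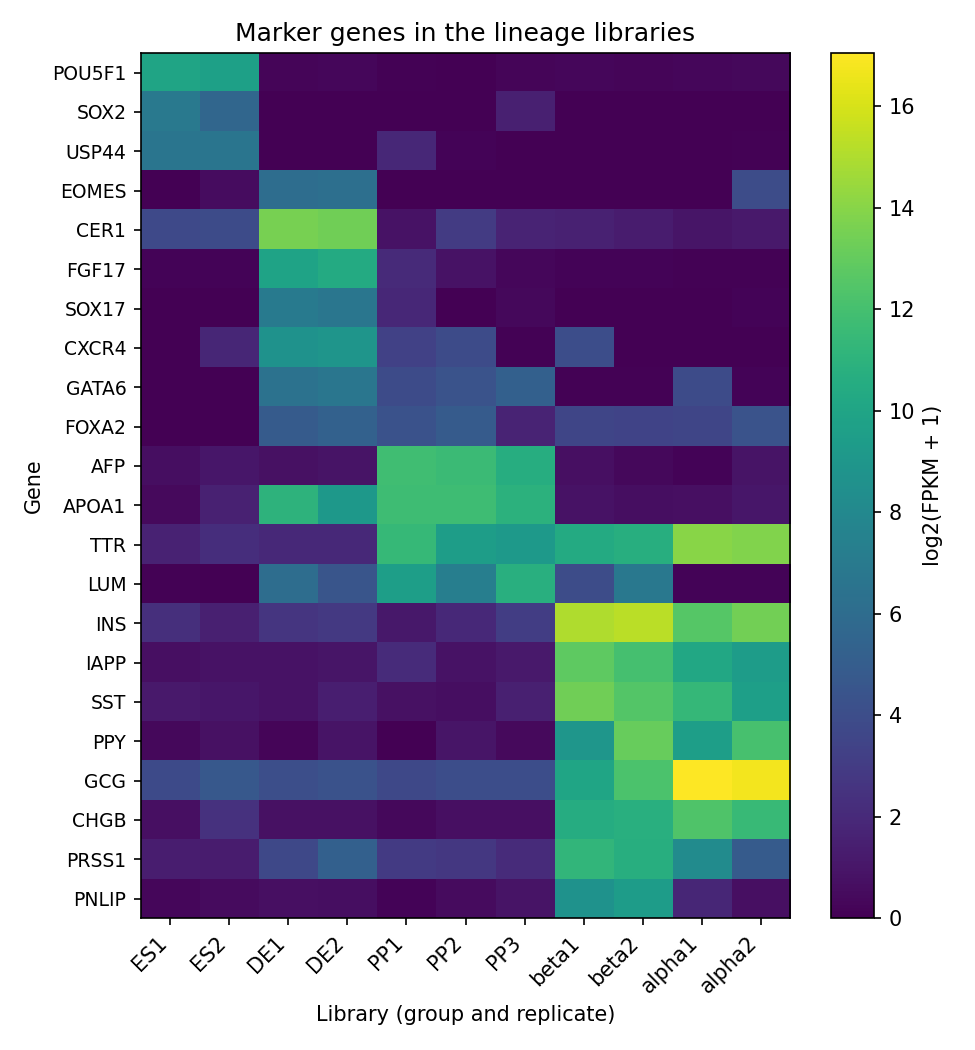
Heat map of log2(FPKM + 1) for 22 marker genes in the 11 lineage libraries, grouped by stage. By group mean, pluripotency genes were highest in ES, CER1 and the streak genes in DE, the liver proteins AFP and APOA1 in PP and hormones in the islet libraries. GCG and TTR were highest in alpha and INS in beta.

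In the lncRNA table, 112 transcripts were called between DE and ES, 72 higher and 40 lower in DE, with 312 under an unadjusted p of 0.05. An assembled transcript on chromosome 3 at 146109165 to 146132935 in hg19, TCONS_l2_00019562, lying 18139 bases from PLSCR2, was at 249 and 241 FPKM in DE and listed at 0 in both ES libraries (adjusted p = 0.000354). GATA6-AS1, on chromosome 18 at 19746940 to 19747903 and 1512 bases from GATA6, was at 20.6 and 28.6 FPKM in DE (ENST00000584373.1) and at 0 in both ES libraries, a call that upper-quartile scaling lost. TCONS_00018089 on chromosome 10 and AC104257.1 on chromosome 8 were at 47.5 and 26.2 and 19.3 and 39.6 FPKM in DE (ENST00000524275.1 for the latter). In the other direction AC009055.2 (ENST00000565901.1, chromosome 16) was at 526 and 385 FPKM in ES and 0 in both DE libraries. AC064802.1 on chromosome 8 and LINC00678 on chromosome 11 fell by 7.69 and 7.28 (ENST00000521523.1 and ENST00000527083.1), and the ESRG transcript ENST00000583516.1 by 7.28. Of the called transcripts, 22 of 72 higher and 8 of 40 lower overlapped a listed gene, against 1803 of 2924 (61.7%) tested. The count was 87, 200, 124 or 107 without ES 1, ES 2, DE 1 or DE 2, and 1, 0, 1 or 1 of 10 named transcripts lost its call. The excess of rises turned without ES 1 (33 higher, 54 lower) and ES 2 (85 higher, 115 lower).

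Between PP and DE, 106 lncRNA transcripts were called, 22 higher and 84 lower in PP (384 under an unadjusted p of 0.05); upper-quartile scaling, which shifted the median by -0.125, gave 4 higher and 61 lower. TCONS_00018519, on chromosome 10 at 54785024 to 54789855, was at 179, 139 and 68.4 FPKM in PP (adjusted p = 0.000455). LINC02381 on chromosome 12 (ENST00000508564.1) was at 125, 111 and 178 FPKM and LHFPL3-AS2 on chromosome 7 (ENST00000453666.1) at 101, 75.1 and 24.2. AL117348.1 (ENST00000513672.1), which overlaps LEFTY2, fell by 8.78 from 457 and 419.9 FPKM. TCONS_l2_00019562 fell by 7.83, and AC106864.1 (ENST00000509938.1), which overlaps LARP7, by 7.61. The stem cell lncRNA LINC00458 (ENST00000423442.1) was still at 119 and 139 FPKM in DE, against 141 and 189 in ES, and fell by 6.76 to PP. Of those called, 8 of 22 higher and 25 of 84 lower overlapped a listed gene. The excess of falls depended on the libraries: without PP 1, PP 2 or PP 3 there were 46, 78 or 75 higher and 72, 78 or 76 lower, and without DE 1 or DE 2 there were 10 or 7 higher and 104 or 90 lower. Of 10 named transcripts 1 lost its call without DE 1, DE 2 or PP 1, and 0 without PP 2 or PP 3.

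Alpha cells set against PP gave 54 lncRNA calls, 25 higher and 29 lower (472 under an unadjusted p of 0.05), and upper-quartile and quantile scaling, which shifted the median of -0.472 by 0.38 and 0.344, gave 96 higher with 8 lower and 53 higher with 38 lower. AC022364.1 on chromosome 12 (ENST00000473753.2) was at 27.4 and 33.3 FPKM in alpha and LINC00271 on chromosome 6 (ENST00000438618.2) at 14.3 and 34.5, and HI-LNC542 on chromosome 5 rose by 4.89. LINC02381, TCONS_00018519 and LHFPL3-AS2 fell to 0 in both alpha libraries (adjusted p = 0.00358, 0.00216 and 0.00594, with ENST00000508564.1 and ENST00000453666.1 for the named genes). The count was 31, 102, 123, 75 or 56 without PP 1, PP 2, PP 3, alpha 1 or alpha 2, and 4, 1, 0, 4 or 4 of 10 named transcripts lost their call; without alpha 1 or alpha 2 the balance turned, to 57 higher with 18 lower and 45 higher with 11 lower. Overlap with a listed gene was seen in 15 of 25 higher and 9 of 29 lower transcripts.

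Beta against PP gave 100 lncRNA calls, 64 higher and 36 lower (473 under an unadjusted p of 0.05), while upper-quartile scaling gave 32 higher and 5 lower; it and quantile scaling shifted the median of -0.298 by 0.201 and 0.263. A transcript overlapping FLJ43390 on chromosome 14, ENST00000554895.1, was at 60.7 and 107 FPKM in beta and 0 in all 3 PP libraries. PLBD1-AS1 on chromosome 12 (ENST00000542401.1) was at 31.3 and 21.1 FPKM and the MEG3 transcript ENST00000452120.2 at 25.96 and 30.97, a call that upper-quartile scaling lost. Overlap with a listed gene held for 36 of 64 higher and 14 of 36 lower. Without PP 1, PP 2, PP 3, beta 1 or beta 2 the count was 106, 152, 161, 127 or 139, and 1, 1, 1, 2 or 2 of 10 named transcripts lost their call. The balance turned without PP 1, PP 2 or PP 3, to 49, 55 or 57 higher and 57, 97 or 104 lower, and with pseudocount 0.1, to 64 higher and 95 lower. Between beta and alpha 56 were called, 40 higher and 16 lower in beta (226 under an unadjusted p of 0.05), against 35 with 46 and 36 with 24 under upper-quartile and quantile scaling. PLBD1-AS1 was listed at 0 in both alpha libraries, AC022364.1 (ENST00000473753.2) at 0 in both beta libraries, and LINC00271 (ENST00000438618.2) fell by 4.32; ZNF674-AS1 and FGF7P3 were called higher on the original scale only. This count was 112, 114, 77 or 44 without beta 1, beta 2, alpha 1 or alpha 2, where 1, 2, 2 or 4 of 10 named transcripts lost their call, and the balance turned without alpha 1 (29 higher, 48 lower) and alpha 2 (16 higher, 28 lower). Overlap with a listed gene held for 21 of 40 higher and 8 of 16 lower.

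Stage-high lncRNAs, called above each of the other 4 lineage groups, numbered 161: 38 in ES, 62 in DE, 13 in PP, 36 in beta and 12 in alpha. The DE set was led by AL117348.1 at 438 ± 26.3 FPKM, TCONS_l2_00019562 at 245 ± 5.85 and TCONS_00011198 at 196 ± 30.0 (SD, n = 2). In the PP set LINC02381 was at 138 ± 35.5 FPKM (n = 3), and TCONS_00018519, TCONS_00018520 and 2 further assembled transcripts, all on chromosome 10 near 54785024, came from the same region. The beta set held PLBD1-AS1, LINC00641, LINC00839, PAX8-AS1, MEG8 and the MEG3 transcript TCONS_00090076_MEG3. Other MEG3 transcripts were higher in an alpha library than in either beta library. The alpha set held AC022364.1, LINC00271 and TPT1-AS1. Stage-high genes numbered 316, 42 in ES, 64 in DE, 130 in PP, 65 in beta and 15 in alpha. Acinar PNLIP, CELA2A and AMY2A led the beta genes, so acinar cells may be a source of the beta set. PP had 3 libraries against 2 in each other group, which favours calls there. The median gene was also lower in the islet libraries than in PP, by -1.144 in alpha and -0.708 in beta. The lncRNA total was 97 without alpha 2, and the gene total was 181, 468, 106, 102 and 197 without ES 1, ES 2, DE 1, DE 2 and PP 1.

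The knockdown experiment asks what follows the loss of the lncRNA DEANR1 and of FOXA2 in endoderm. LINC00261 (DEANR1) was at 18.7 and 19.3 FPKM in WT, 3.17 and 4.04 in DEANR1KD and 1.61 and 4.10 in FOXA2KD. FOXA2 was at 48.9 and 51.05 FPKM in WT, 19.6 and 21.4 in DEANR1KD and 5.43 and 14.4 in FOXA2KD, so each knockdown lowered both genes in both libraries. In FOXA2KD the log2 differences were -2.36 ± 0.38 for FOXA2 (adjusted p = 0.00541) and -2.46 ± 0.31 for LINC00261 (adjusted p = 0.00264). In DEANR1KD they were -2.13 ± 0.31 for LINC00261 (adjusted p = 0.00617), a call lost without WT 2, and -1.25 ± 0.38 for FOXA2 (adjusted p = 0.0482). The call on FOXA2 in DEANR1KD lay close to the threshold and was lost without WT 1, WT 2, DEANR1KD 1 or DEANR1KD 2. FOXA2 differed between the knockdowns by 1.11 ± 0.38 (adjusted p = 0.181). For LINC00261 as for FOXA2 the level left in FOXA2KD 2 was more than 2 times that in FOXA2KD 1. Other genes near FOXA2 changed less: XRN2 rose by 0.42, GZF1 by 0.33 and NXT1 by 0.29 in FOXA2KD, NAPB and THBD were not called, and in DEANR1KD only FOXA2 and LINC00261 were called in the neighbourhood. Over the 7 genes of the neighbourhood that were tested, which include FOXA2 and LINC00261, the median was 0.10 but the mean -0.63 in FOXA2KD, and 0.15 and -0.38 in DEANR1KD, with camera up in each (adjusted p = 0.949 and 0.77). The calls on GZF1 and NXT1 were lost without WT 1 or WT 2, that on XRN2 without WT 2 and that on NXT1 without FOXA2KD 2.

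In FOXA2KD most definitive endoderm genes fell and most pluripotency and mesenchyme genes rose, but no list passed with an estimated correlation. The endoderm factor GATA4 went from 86.4 ± 3.93 FPKM in WT to 17.4 ± 8.93 (n = 2 each), a difference of -2.34 ± 0.32 (adjusted p = 0.00325). GATA6 fell by 1.60 and SOX17, chosen after its values were seen, from 139 and 137 to 21.1 and 52.1. POU5F1 rose from 88.02 ± 4.85 to 622 ± 116 FPKM (2.79 ± 0.14, adjusted p = 0.000304). FGF2 and NANOG rose by 2.84 and 2.03, and GDF3 from 11.6 and 10.6 to 55.3 and 42.02 FPKM. The mesoderm factor T (brachyury) went from 2.85 ± 0.805 to 17.04 ± 4.05 FPKM, SP5 rose by 1.80 and the WNT antagonist DKK1 by 2.21. Vimentin, VIM, rose from 101 ± 4.46 to 627 ± 4.72 FPKM, TAGLN by 2.58 and THY1 by 2.84. The neural factor SOX3 rose by 2.88 and the Notch target HES1 by 2.12. CER1 was at 1106 and 2956 FPKM against 4898 and 4805 in WT, FGF17 at 72.8 and 224 against 628 and 639, and CXCR4 at 20.1 ± 21.3 against 75.7 ± 4.31; the calls on CER1 and CXCR4 were lost without WT 1 or WT 2, and under quantile and upper-quartile scaling in that order. DLK1, KRT19 and GATA3 fell by 3.56, 2.31 and 2.10. The largest differences by rule were entries for small RNAs listed at 0 in a group, such as SNORD65 at 813 and 247 FPKM against 0 in both WT libraries and MIR302B at 0 against 235 and 119.9, which a library of this kind measures poorly. Without small RNAs, a step chosen after the data were seen, osteopontin, SPP1, led the rises (2.10 ± 0.257 to 160.0 ± 97.04 FPKM), and other large rises were in the actin ACTG2 (1.09 ± 0.0153 to 65.9 ± 0.371), IGFBP7 (4.48) and ANXA1 (4.32). APOA2, S100A14 and EPSTI1 then led the falls, by 4.32, 4.19 and 4.15. Of 13195 genes 6717 were called, 3177 higher and 3540 lower (7698 under an unadjusted p of 0.05), and 1709 genes, called or not, differed by at least 1 in either direction. The count was 4081, 3701, 5520 or 7207 without WT 1, WT 2, FOXA2KD 1 or FOXA2KD 2, and 22, 23, 9 or 8 of the 111 named genes lost their call.

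All list results in this contrast were lost with an estimated correlation, where adjusted p was at least 0.466. The definitive endoderm list fell in 18 of 21 cases and rose in 1, 20 and 1 adjusted over the list alone (camera adjusted p = 5.17e-05, but adjusted p = 0.482 with an estimated correlation). Of 20 pluripotency genes 12 rose and 4 fell, 13 and 4 adjusted over the list alone (0.0107, but adjusted p = 0.531 with an estimated correlation). Of 14 proliferation genes 13 rose, also 13 adjusted over the list alone, led by PCNA (1.34) and TYMS (1.15; 1.77e-05, but adjusted p = 0.466 with an estimated correlation). APOA2, APOA1, HNF4A and TBX3, the 4 hepatic genes tested, fell, also adjusted over the list alone (0.0107, but adjusted p = 0.466 with an estimated correlation). Mesenchyme genes rose in 5 of 8 cases (0.0107), and adjusted over the list alone 5 rose and 1 fell (adjusted p = 0.466 with an estimated correlation). Streak genes rose in 10 of 14 cases and fell in 3 (0.0221, but adjusted p = 0.466 with an estimated correlation), WNT targets in 8 of 13 and 2 (0.0407, likewise adjusted p = 0.466 with an estimated correlation) and neural genes in 4 of 5 and 1 (0.0485, likewise adjusted p = 0.466 with an estimated correlation), with the same numbers for these 3 lists adjusted over the list alone. Pancreatic progenitor genes fell in 9 of 11 cases and rose in 2, the same adjusted over the list alone (0.0373, but adjusted p = 0.466 with an estimated correlation). Even housekeeping genes moved, 8 of 16 rising and 1 falling, 7 and 3 under quantile scaling (0.0407, but adjusted p = 0.466 with an estimated correlation), with GAPDH higher by 0.61. Of 19 Nodal and Activin genes 9 fell and 2 rose (camera adjusted p = 0.141), FOXH1 among the falls.

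DEANR1KD moved many of the same genes, mostly by less. POU5F1 rose from 88.02 ± 4.85 to 409 ± 13.02 FPKM (2.20 ± 0.14, adjusted p = 0.00081), GDF3 by 2.06, FGF2 by 2.31 and ZFP42 by 1.87. FOXA3 fell from 19.5 ± 0.577 to 6.22 ± 0.250 FPKM (-1.51 ± 0.34, adjusted p = 0.0203), and the channel gene TRPA1 fell by 1.29. SOX17, chosen after its values were seen, was at 77.9 and 90.3 FPKM against 139 and 137 (-0.71 ± 0.39, adjusted p = 0.192). VIM, TAGLN and THY1 rose by 2.51, 2.49 and 1.86. SOX3 and HES1 rose by 2.45 and 1.64, and DKK1 by 1.09. FOXH1, a partner of the Nodal signal, fell from 84.8 ± 5.17 to 31.9 ± 2.77 FPKM, DLK1 by 2.47 and GATA3 by 1.64. PAX6 and DDX58 fell by 1.35 and 0.65. By rule SPP1 was among the largest rises even beside small RNAs, from 2.10 ± 0.257 to 184 ± 2.70 FPKM (adjusted p = 0.00102), with ANXA1 at 4.36 and ACTG2 at 4.29. Without small RNAs, S100A14, BST2, CCL2 and STMN2 led the falls, by 3.71, 2.96, 2.73 and 2.62. The stem cell lncRNA gene ESRG rose from 5.25 ± 0.1805 to 70.7 ± 1.53 FPKM. In all, 5337 genes were called, 2597 higher and 2740 lower (6812 under an unadjusted p of 0.05), and 1068 genes, called or not, differed by at least 1. Without WT 1, WT 2, DEANR1KD 1 or DEANR1KD 2 the count was 2167, 1575, 1759 or 1879, and 31, 34, 32 or 34 of the 99 named genes lost their call; rises outnumbered falls without WT 1 (1156 and 1011), WT 2 (850 and 725) and DEANR1KD 1 (957 and 802).

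As a list, definitive endoderm genes were lower in DEANR1KD without passing camera (6 of 21 fell, 5 adjusted over the list alone; adjusted p = 0.0821). Pluripotency genes rose in 11 of 20 cases and fell in 3, 13 and 3 adjusted over the list alone (0.00971, but adjusted p = 0.533 with an estimated correlation). Proliferation genes rose in 11 of 14 cases, also 11 adjusted over the list alone (0.000715, but adjusted p = 0.533 with an estimated correlation), and 6 of 14 immediate early and stress genes rose, FOS and GADD45B among them, also 6 adjusted over the list alone (0.00971, but adjusted p = 0.533 with an estimated correlation). Mesenchyme genes rose in 5 of 8 cases and fell in 2 (0.0903), and pancreatic progenitor genes rose in 2 of 11 and fell in 7 (0.0903). Housekeeping genes rose in 7 of 16 cases, with 4 rising and 2 falling under quantile scaling (0.0903).

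Set directly against each other, the knockdowns differed at 288 genes, 185 higher and 103 lower in DEANR1KD, with 2815 under an unadjusted p of 0.05. The count was 842 without small RNAs (chosen after seeing the data), 36 with no filter, 181 with a filter at 5 FPKM and 22 with only these groups in the fit. The cystatins CST1 and CST2 stood higher in DEANR1KD, CST1 at 113 ± 9.71 FPKM against 9.54 ± 7.56 (3.65 ± 0.49, adjusted p = 0.0368). APOA1 was at 12.5 ± 1.85 FPKM against 1.81 ± 0.951, FOXQ1 at 17.4 ± 1.47 against 3.52 ± 1.76 and LGR5 at 14.1 ± 0.0938 against 3.77 ± 1.61. IGFBP5 and MYOF were higher by 1.67 and 1.46; NUDT4P1 and LIFR, higher by 1.64 and 1.53, lost their call under either scaling. Lower in DEANR1KD were T at 5.10 ± 0.435 FPKM against 17.04 ± 4.05, CDH11 (-1.56), SP5 (-1.18), DKK1 (-1.12), FGF4 (-1.45), PDK1 (-1.24) and THY1 (-0.98). HSPA1A and DDX58 were higher in DEANR1KD by 0.74 and 0.67, and MCM2 lower at -0.66; quantile scaling ended the call on DDX58. Small RNAs made up 17 of the 288. CST1, CST2, APOA1, FOXQ1, LGR5, T and CDH11 all lost their call when DEANR1KD 1 was left out. The count was 22 without WT 1 or without WT 2, whose spread enters the pooled variance. It was 15, 17, 401 or 1573 without DEANR1KD 1, DEANR1KD 2, FOXA2KD 1 or FOXA2KD 2, and 37, 38, 5 or 0 of the 49 named genes lost their call; without DEANR1KD 2 only 5 were higher and 12 lower. Definitive endoderm genes stood higher in DEANR1KD than in FOXA2KD, 1 of 21 called and 11 adjusted over the list alone (camera adjusted p = 8.68e-08, but adjusted p = 0.547 with an estimated correlation). Hepatic genes were higher in 1 of 4 cases, 4 adjusted over the list alone (0.00059, but adjusted p = 0.414 with an estimated correlation), and 2 of 14 immediate early and stress genes were higher, 6 with 1 lower adjusted over the list alone (0.0173, but adjusted p = 0.414 with an estimated correlation). Mesenchyme genes were lower in 3 of 8 cases, also 3 adjusted over the list alone (0.000909, but adjusted p = 0.414 with an estimated correlation). WNT targets were lower in 3 of 13 and higher in 1, 6 and 1 adjusted over the list alone (0.00575, but adjusted p = 0.486 with an estimated correlation). Streak genes were lower in 3 of 14, and adjusted over the list alone 5 lower and 1 higher (0.0122, but adjusted p = 0.547 with an estimated correlation). MCM2 was the called gene of 14 proliferation genes, with 2 lower adjusted over the list alone (0.000331, but adjusted p = 0.547 with an estimated correlation).

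Across genes, the knockdown profiles resembled each other, with the WT libraries shared between them. Genes higher in both numbered 2244 and lower in both 2353, while 9 were called in opposite directions. Independent calls would give 625 higher in both, 735 lower in both and 1356 in opposite directions, and unchanged groups set against the same WT libraries gave 0.04, 0.04 and 0.01 in simulation. Across 13195 genes, which are not independent replicates, the correlation of the log2 differences was 0.802 (0.494 simulated), the covariance 0.444 (0.0447 simulated) and the share with the same sign 86.4% (66.6% simulated). The excess over the simulation can still hold a part from the shared WT libraries, which were not split between the contrasts. The number called in the same direction in both, 4597, was 1894, 1442, 1638 and 1761 without WT 1, WT 2, DEANR1KD 1 and DEANR1KD 2. The median size of a change was 0.347 in FOXA2KD and 0.287 in DEANR1KD. POU5F1, VIM and SPP1 were among the genes higher in both, and DLK1 and S100A14 among those lower in both.

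**Figure D3:**
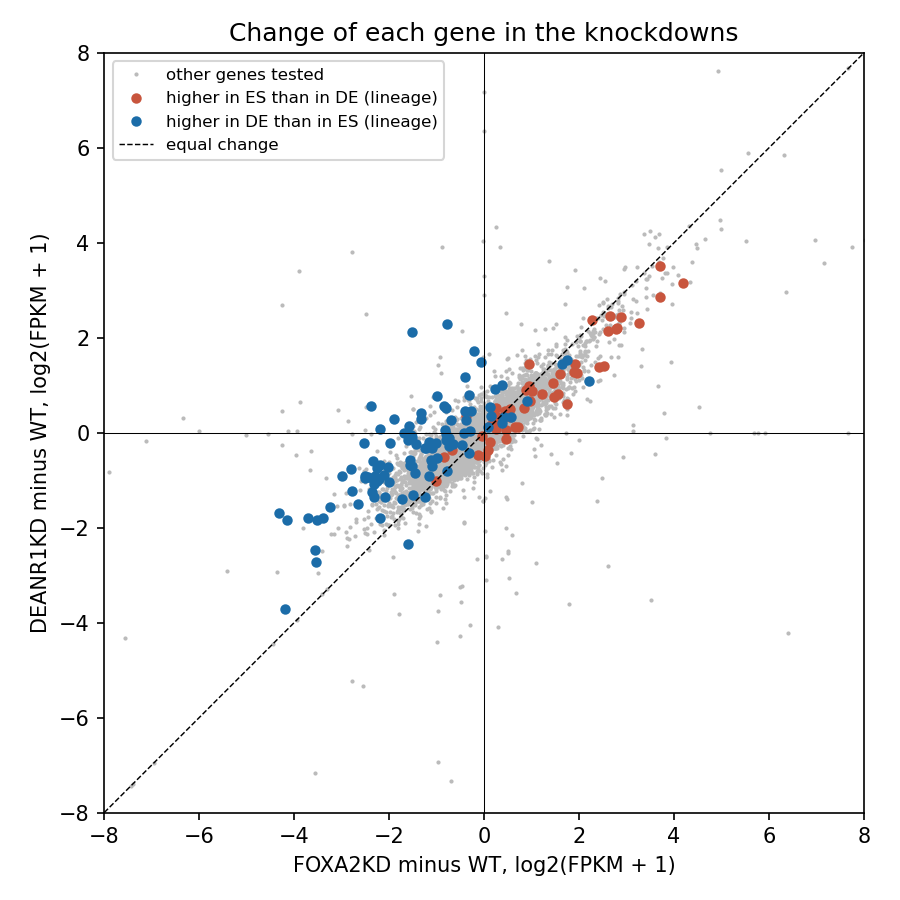
Log2 difference from WT in DEANR1KD (y axis) against that in FOXA2KD (x axis) for 13166 genes (5 lie outside the axes), with a point for each gene genes higher in DE than in ES in blue and genes higher in ES in red. Most points lie near the diagonal, and the blue points are further below WT in FOXA2KD than in DEANR1KD.

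The signatures of the lineage step were then read in the knockdown libraries, which were not used to choose them; they were chosen on the ES and DE libraries and are not independent of that comparison. Of 111 DE-high genes 98 were tested, and in FOXA2KD 75 of them fell and 7 rose, with a median of -1.44 (interquartile range -2.26 to -0.70; camera p = 9.7e-11, p = 0.344 with an estimated correlation, fry p = 0.0157). In DEANR1KD 30 fell and 15 rose, with a median of -0.29 (interquartile range -0.95 to 0.28; camera p = 0.0354, p = 0.74 with an estimated correlation, fry p = 0.285). The DE-high genes were higher in DEANR1KD than in FOXA2KD by a median of 0.96 (interquartile range 0.48 to 1.56; camera p = 6.75e-23, p = 0.186 with an estimated correlation, fry p = 0.0392). Of 61 ES-high genes 48 were tested: 32 rose and 4 fell in FOXA2KD (median 0.94; camera p = 4.77e-09, p = 0.143 with an estimated correlation), and 28 rose and 4 fell in DEANR1KD (median 0.71; camera p = 2.1e-07, p = 0.179 with an estimated correlation). Between the knockdowns their median was -0.36 in DEANR1KD (camera p = 1.36e-06, p = 0.202 with an estimated correlation). The camera call on the DE-high genes in DEANR1KD was lost when the signature was chosen without ES 1, ES 2, DE 1 or DE 2, with medians of -0.66, -0.10, -0.23 and -0.20.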

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

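Of the tests in this part, the direct comparison of the knockdowns and the test of genes outside the range from WT to FOXA2KD were written before their results were seen, while the 2 tests on endoderm-only genes were chosen afterwards. A bound in those 2 tests was also revised once after the FOXA2KD value was known, from fewer than 3 genes higher to none.

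The DEANR1KD and FOXA2KD libraries differed from each other in a direct limma test, which is why these results are taken up here: 288 genes were called, 185 higher and 103 lower in DEANR1KD. The DE-high signature stood higher in DEANR1KD by a median of 0.963 (camera p = 6.75e-23, p = 0.186 with an estimated correlation). CST1, APOA1 and LGR5 stood higher in DEANR1KD than in FOXA2KD, and T and SP5 lower, though LINC00261 fell in each. The 288 depends on the genes kept and on single libraries. It was 842 without small RNAs (chosen after seeing the data), 36 with no filter, 181 with a filter at 5 FPKM and 22 with only these groups in the fit. Without DEANR1KD 1, DEANR1KD 2, FOXA2KD 1 or FOXA2KD 2 it was 15, 17, 401 or 1573, and without WT 1 or WT 2, which enter through the pooled variance, it was 22 each time; the excess of higher genes turned without DEANR1KD 2 (5 higher, 12 lower). The signature median ranged from 0.236 to 1.403 over the libraries left out and the signatures chosen without 1 library, and was 1.439 with up to 50 genes. The FOXA2KD libraries were also less alike than the others: the median squared difference between replicates, over the variance expected from counting, was 16.74, against 6.07 in WT and 5.06 in DEANR1KD.

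For the lower endoderm genes in the knockdown libraries, fewer cells reaching endoderm as the only cause in the DEANR1 knockdown could not be decided. The 33 endoderm-only genes were chosen as low in ES and high in DE and WT, so cells of another fate could express them as well. They include the knockdown targets FOXA2 and LINC00261, which fell in each knockdown. In DEANR1KD 10 of the 33 fell and 4 were called higher (range -2.47 to 2.29, median -0.55). A loss of endoderm cells would not raise those 4 unless other cells express them. Each was at least 2 times WT in every pair of libraries. These were ANKRD1, at 26.02 and 24.3 FPKM in WT and 72.9 and 72.00 in DEANR1KD, CST1 (25.9 and 24.4, then 106 and 119.9), NPPB (74.8 and 78.2, then 359.9 and 396) and LOC729739. Their lowest DEANR1KD library was 2.77, 4.10, 4.60 and 2.72 times the highest WT library, in that order. Without a WT or DEANR1KD library only LOC729739 stayed called higher, and fewer genes were called lower. Without a FOXA2KD library, whose spread enters the pooled variance, more of the 33 genes were called higher and more were called lower. SOX17 (77.9 and 90.3 FPKM against 139 and 137 in WT) and GATA4 (41.6 and 46.0 against 83.6 and 89.2), for example, were not called. Expression of the 4 genes by cells of another fate was not tested. In the FOXA2 knockdown 26 fell and 2 were called higher, EOMES and LOC729739 (range -4.15 to 1.63, median -1.60; 1 higher without WT 2 and 4 without FOXA2KD 1), so fewer cells reaching endoderm as the only cause cannot be told apart from loss of expression within cells there, since 2 genes are too few to decide. A smaller loss of FOXA2 as the only cause of the DEANR1 knockdown changes cannot be told apart from further effects: 25.7% of the 288 genes (74) had a called change in DEANR1KD outside the range from WT to FOXA2KD, above the bound of 20% set beforehand, but only 203 of 1573 (12.9%) without FOXA2KD 2, with 126 of 401 without FOXA2KD 1, and 5 of 15, 8 of 17, 10 of 22 and 12 of 22 without DEANR1KD 1, DEANR1KD 2, WT 1 and WT 2. Chosen after seeing the data, the share was 157 of 842 (18.6%) without small RNAs, 15 of 36 with no filter and 46 of 181 with a filter at 5 FPKM, and neither a response that peaks at a partial loss nor effects of the knockdown reagents were tested.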

How the results depend on the processing

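No called gene among those named and no signature median changed direction. Of 692 pairs of a named gene and a contrast, 568 were called; over 9872 combinations with an alternative, 8656 gave the same verdict, 1165 lost a call and 51 gained one. In every alternative 281 of the 568 kept their call, and 287 lost it in at least 1. Apart from leaving out single libraries, which is not ranked here, fitting only the groups compared ended most calls (159), followed by the replicate block (121), no filter (83), a minimum difference of 1 (65), pseudocount 0.1 (55), quantile scaling (38), upper-quartile scaling (31), pseudocount 5 (24), no trend (16) and a filter at 5 FPKM (12).

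The balance of higher and lower calls turned in several contrasts. For lncRNAs, DE against ES (72 higher, 40 lower) gave 33 and 54 without ES 1 and 85 and 115 without ES 2, and PP against DE (22 and 84) came level at 78 and 78 without PP 2. Alpha against PP (25 and 29) gave 96 and 8 with upper-quartile scaling, 53 and 38 with quantile scaling, 14 and 12 with pseudocount 5, 57 and 18 without alpha 1 and 45 and 11 without alpha 2. Beta against PP (64 and 36) gave 64 and 95 with pseudocount 0.1, 44 and 52 with a filter at 5 FPKM, 3 and 9 with only those groups, and 49 and 57, 55 and 97, and 57 and 104 without PP 1, PP 2 and PP 3. Beta against alpha (40 and 16) gave 35 and 46 with upper-quartile scaling, and 29 and 48, and 16 and 28 without alpha 1 and alpha 2. For genes, PP against DE (214 and 133) gave 41 and 51 without DE 2. FOXA2KD (3177 and 3540) gave 2510 and 2472 with a filter at 5 FPKM. DEANR1KD (2597 and 2740) gave 2619 and 2589 with pseudocount 0.1, 2105 and 1819 with that filter, 472 and 458 with a minimum difference of 1, and 1156 and 1011, 850 and 725, and 957 and 802 without WT 1, WT 2 and DEANR1KD 1. Between the knockdowns (185 and 103), 5 and 12 were called without DEANR1KD 2.

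FOXA2 between DE and ES was no longer called with pseudocount 5 or with only those groups in the fit. In DEANR1KD it was no longer called with pseudocount 0.1, no filter, a filter at 5 FPKM or no trend, and was called under both scalings. FOXA2 and LINC00261 in FOXA2KD were called in every alternative run.

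Pseudocount 0.1 gave 109 genes between DE and ES, 126 and 159 lncRNAs for alpha and beta against PP, and 194 stage-high genes. Pseudocount 5 gave 26, 62 and 34 lncRNAs for alpha against PP, beta against PP and beta against alpha, and 84 stage-high lncRNAs. With no filter there were 32 lncRNAs for alpha against PP, 107 stage-high lncRNAs and 36 genes between the knockdowns. A filter at 5 FPKM gave 63, 61 and 87 lncRNAs for DE against ES, PP against DE and alpha against PP, 97 stage-high lncRNAs and 181 genes between the knockdowns. Quantile scaling gave 1736 genes and 91 lncRNAs for alpha against PP. Upper-quartile scaling gave 63, 65, 104 and 37 lncRNAs for DE against ES, PP against DE, alpha against PP and beta against PP. Apart from the changed number of genes tested under the filters, the cause was not tested.

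With only the compared groups in the fit, fewer libraries set the variance. Limma then called 0 genes for DE against ES (1188 at an unadjusted p under 0.05) and 0 for beta against alpha (633). It called 0, 19, 19, 12 and 0 lncRNAs in the order of the lineage contrasts (152 and 78 unadjusted where 0 were called), and 22 genes between the knockdowns. A minimum difference of 1 left 1575 genes in FOXA2KD, 930 in DEANR1KD and 84 between them. Chosen after seeing the data, leaving out small RNAs gave 842 genes between the knockdowns, and summing overlapping transcripts gave 30 lncRNA loci between beta and alpha.

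The replicate block, which assumes that libraries of the same number belong together, gave 74, 154, 1266, 748 and 23 genes in the order of the lineage contrasts. For lncRNAs it gave 53 (26 higher, 27 lower), 102 (45 and 57), 5 (0 and 5), 89 (36 and 53) and 0 (216 unadjusted for the last, limma), 49 stage-high lncRNAs and 130 stage-high genes, and 6700, 5303 and 21 genes in the knockdown contrasts. Differences between replicate numbers correlated from -0.1 to 0.09 across lineage contrasts and from -0.01 to 0.09 in the knockdown libraries, so no pairing by number was seen over all genes; single stress and REG genes of the islet libraries did differ by number in the same direction in beta and alpha.

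Leaving out 1 library at a time gave 60 to 651, 92 to 294, 1508 to 2268, 824 to 1040 and 154 to 488 genes in the order of the lineage contrasts. For lncRNAs the ranges were 87 to 200, 97 to 156, 31 to 123, 106 to 161 and 44 to 114. In the knockdown libraries they were 3701 to 7207 for FOXA2KD, 1575 to 2167 for DEANR1KD and 15 to 1573 between them, and 1442 to 5489 genes were called the same way in both. Stage-high genes numbered 102 to 468 and stage-high lncRNAs 97 to 232. Signature medians over libraries left out, or signatures chosen without 1 library, were -1.816 to -0.394 in FOXA2KD, -0.661 to -0.101 in DEANR1KD and 0.236 to 1.403 between them for DE-high genes. For ES-high genes they were 0.479 to 1.896, 0.328 to 1.288 and -0.591 to -0.191. The ranges of calls given for a contrast cover only libraries of the groups it compares. The range for genes called the same way in both knockdowns covers each of the 6 knockdown libraries left out, so it can exceed the range for DEANR1KD.

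The call on the DE-high signature in DEANR1KD was lost under several choices: its median was -0.306 with pseudocount 0.1, -0.232 with no filter, -0.32 with upper-quartile scaling and -0.636 with up to 50 genes, and -0.661, -0.101, -0.232 and -0.201 with signatures chosen without ES 1, ES 2, DE 1 and DE 2 (an alternative chosen after seeing the data), none under 0.05 by camera (p from 0.00246 to 0.398 over all alternatives). With an estimated correlation, 3, 6, 4, 5 and 2 lists passed in the order of the lineage contrasts, and 0 in each knockdown contrast.

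Depth limits low levels: at 11.1 (units of 1e6 fragments, PP 3), 1 fragment on a transcript of 2 kilobases is 0.045 FPKM. In simulated data, added changes of 4 (log2) were called in 28% of genes between DE and ES, against 100% in FOXA2KD.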

Other observations

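Islet libraries of the same sort differed in stress genes. The chaperones HSPA1A, DNAJB1, HSPH1 and HSPA5 were at 11.5 and 386, 55.1 and 2068, 5.07 and 285 and 284 and 1496 FPKM in the beta libraries and at 3.36 and 289, 56.1 and 1246, 13.7 and 119 and 381 and 1655 in the alpha libraries. The chemokines IL8 and CXCL2 showed the same split in beta (117 and 4783, and 16.1 and 767) and in alpha (0.172 and 1063, and 0 and 34.7). REG1A and REG1B went the other way, at 1938 and 92.2 and at 510.2 and 0.653 FPKM in beta, and at 602 and 17.7 and at 86.4 and 0.820 in alpha. PLVAP was at 0 and 234 FPKM in alpha. These genes were chosen after their values were seen, and no test was run between single libraries.

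Outside the named comparisons, the nuclear lncRNA MALAT1 (ENST00000544868.1) stood at 124 and 40.8 FPKM in ES, 119 and 168 in DE, 536, 345 and 300.4 in PP, 1318 and 1709 in beta and 1451 and 1085 in alpha. LINC00479 (ENST00000412102.1) was at 15.5 and 14.5 FPKM in DE and 10.7 in alpha 2, at 1.83 in PP 2, and at or near 0 in the other lineage libraries.

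All tests in the remaining paragraphs were chosen after the levels of the hormone and acinar genes were seen.

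Islet hormones were listed at low level in every stem cell and progenitor library, except PPY in PP 1: GCG from 11.9 to 24.4 FPKM, INS from 1.15 to 7.49 and SST from 0.583 to 1.87 over the ES, DE and PP libraries. Hormone transcription in the differentiating cells could not be decided. In WT of the knockdown series 0 of 5 hormones reached 0.5 FPKM, but that separate series has no ES or PP library. Reads of the islet libraries counted in the other libraries of the pool are a candidate explanation: per 100000 of the summed islet FPKM, the median level in ES, DE and PP was 6.2 for GCG, 4.27 for INS, 5.1 for SST, 2.56 for PPY and 6.21 for IAPP, a spread of 2.43 times over hormones whose islet levels differ far more. Levels of this size in ES, DE or PP may therefore say nothing on endocrine expression, and RNA carried over between samples was not tested.

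Acinar enzymes were abundant in the sorted beta libraries, and acinar cells in the beta sorts are a candidate source: 17 of 18 genes of a list written beforehand were at 5 FPKM or more in both beta libraries, against 7 in both alpha libraries and 1, SPINK1, in all PP libraries. The most abundant were PRSS1 at 2432 and 1668 FPKM, REG1A at 1938 and 92.2 and PRSS2 at 1526 and 421; a gate on an antibody to acinar cells would remove them, and the sort named in the labels used HPi2 and HPa1. Acinar cells of 1 composition in sorts of the same number could not be decided: no general pairing by number was seen. Over members at 50 FPKM or more in beta, the alpha to beta ratio spread 283 times in libraries 1 and 639.7 in libraries 2. AMY2A, near the floor in alpha, was lowest in each. Of these members, 15 of 17 in alpha 1 and 4 of 16 in alpha 2 lay within 10 times the level at the median ratio. The others in alpha 1 were PNLIP, at 2.55 FPKM with 60.5 needed, and AMY2A, at 0.09 with 12.1. In alpha 2, 8 were too low to judge, PNLIP was at 0.630 with 8.11 needed and CPB1 at 69.7 with 3.47. RNA released from broken acinar cells, and acinar transcription in beta cells, were not tested.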
